A study of Mus musculus with 6 samples.

How the data were processed

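TH2B is a histone H2B variant made in the testis, where it replaces most of the somatic H2B during meiosis. Its binding to chromatin was measured by ChIP-seq in male germ cells of adult mice. The 6 samples were 3 ChIP libraries and 3 input libraries, with 1 library per group. In mice with 1 tagged copy of the TH2B gene, ChIP was done with an antibody to the HA part of the tag, in spermatocytes (meiotic cells) and in round spermatids (post-meiotic cells) separated on a BSA gradient. The labels' protocol speaks of pooled fractions of both cell types, which was read here as fractions pooled within each cell type, as the cell type labels say. If the types had been mixed, the comparison between them would not hold. In wild-type mice, ChIP was done with an antibody to TH2B itself, in total germ cells. Groups were taken from the cell type, genotype and antibody in the labels and, for the inputs, from the titles. The input of wild-type germ cells carries the TH2B antibody among its labels and is an input by its title, which was followed. If it were a ChIP library, the wild-type folds would not be folds over input.

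Each ChIP sample had 1 list of islands, which are broad enriched regions built by joining neighbouring windows. The islands were called with SICER on the mouse build mm9, per the submitters' processing notes. The window of 200 bp and the gap of 600 bp were read from the names of the deposited lists. The aligner, the software versions and the filters on reads are not given in the sources used here. Each list had 8 columns without a header, and their meaning was read from the values. The authors deposited whole-number counts of ChIP reads and of control reads in each island. The deposited p-value and FDR compared these counts, and every island had an FDR below 0.00999. The fold over control deposited by the authors was checked to be the ratio of the counts divided by 1 constant per list, which was 0.854 in spermatocytes, 0.944 in round spermatids and 0.989 in wild-type germ cells. The lists did not name their control library, which was taken here to be the input of the same cells. The titles of both tagged inputs end in a 2 that the labels do not explain and that the ChIP titles lack, so whether each input was prepared with its ChIP library was not established. Starts were counted from 0 in all lists. Ends were the last base of a window in the tagged lists and the base after it in the wild-type list, so all were brought to 1 convention, and positions are given counted from 1. The tagged lists held 2 and 3 blank lines, which were skipped.

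Depth was known only inside islands, because reads outside them and library totals were not used here. The lists held 2375595, 3061563 and 1872812 ChIP reads in islands for spermatocytes, round spermatids and wild-type germ cells, beside 1966489, 2400549 and 1333472 control reads. With 1 library per group there was no replicate error and no p-value was computed. Shares of islands have exact (Clopper-Pearson) 95% intervals and folds have 95% intervals from the counts of reads. These cover counting error only, and not the spread between animals or library preparations. A list holds called islands alone, so a position outside a list may have reads that did not reach the caller's threshold, and absence from a list was not read as absence of TH2B.

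Overlap was counted with bedtools 2.31.1, with at least 1 bp in common. It was set beside 100 random circular shifts of the islands within each chromosome, each by at least 5% of the span holding islands. A further set of 100 shifts moved every island by 50 to 500 kb either way, to keep the regional density of islands. Overlapping islands of the 2 tagged lists were merged into regions. Within a region the reads of each list were summed over its own islands only, and the fold of round spermatids was divided by that of spermatocytes. The 2 folds of a region can therefore come from stretches that differ in place and length. A change of at least 2-fold was the fixed rule of size. The covered share of chromosome X was divided by that of the 19 autosomes, with chromosome lengths of mm9 from the R package GenomeInfoDb 1.38.1. Other values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

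The overlap was tested on simulated lists with the lengths of the spermatocyte and round spermatid islands, placed at random within chromosomes. The ratios were tested on simulated regions with reads drawn from the spermatocyte islands. Among 15585 islands with 2992 planted overlaps, 3770 overlapping islands were found beside 3754 expected, chance overlaps included. With none planted, 804 overlapped, beside a mean of 800 after shifts. The expected number used the chance rate of the same simulation. Islands placed at random lack the regional clustering of the real lists. These values therefore check the counting only, and not whether shifts give the chance overlap of clustered islands. Among 1987 simulated regions, 193 of 200 regions changed 3-fold and 6 of 1787 unchanged regions, 0.336%, passed the 2-fold rule.

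Alternatives written before the data were examined were a stricter FDR of 0.0001, a fold of at least 2, a length of at least 1000 bp, a reciprocal overlap of 50%, equal numbers of islands, islands per Mb in place of covered length, changes of 1.5-fold and 3-fold, scaled ChIP reads in place of fold, and at least 100 ChIP reads. The rule for named items was also written then. Without gene models of mm9 it took, per list, the 5 islands of highest fold among those with at least 50 ChIP reads and the 5 longest, the 3 of highest fold found in 1 list only, and the 5 shared regions per direction with the largest ratio of folds. Items outside this rule are said to be chosen after the values were seen. The gene table at hand was of another build, so islands were not assigned to genes, the gene lists chosen beforehand and the share of islands at transcription start sites were not analysed here, and positions stand alone.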

Results

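The data were 3 island lists, each from 1 ChIP library of TH2B called against a control library that was taken to be the input of the same cells. HA ChIP of tagged TH2B gave 15585 islands in spermatocytes and 17340 in round spermatids, and anti-TH2B ChIP gave 13582 in wild-type total germ cells. The median island held 104 ChIP reads in spermatocytes, 117 in round spermatids and 119 in wild-type germ cells, beside 79, 84 and 82 reads of input. There were no replicates, and all intervals below are 95% intervals of counting error only.

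TH2B islands were broad and weakly enriched in all 3 lists. They covered 59.2 Mb of the genome in spermatocytes, 63.4 Mb in round spermatids and 37.5 Mb in wild-type germ cells, which was 2.23%, 2.39% and 1.41% of mm9. The median length was 3600 bp in spermatocytes, 3400 bp in round spermatids and 2600 bp in wild-type germ cells. The median fold over input, as deposited by the authors, was 1.51 in spermatocytes, 1.46 in round spermatids and 1.45 in wild-type germ cells. A fold of at least 2 was reached by 1378 spermatocyte islands (8.84%, interval 8.40 to 9.30), 1105 round spermatid islands (6.37%, 6.01 to 6.75) and 849 wild-type islands (6.25%, 5.85 to 6.67). The number of islands grows with depth as well as with binding, so the lists' lengths were not compared as amounts of TH2B. The samples held no HA ChIP of untagged cells and no anti-TH2B ChIP of cells without TH2B. Folds over input were therefore not shown to be specific to TH2B.

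The islands of highest fold with at least 50 ChIP reads were short. In spermatocytes the first was chr16:88907401-88908600 with a fold of 6.15 (interval 3.29 to 12.5, 63 ChIP and 12 input reads), followed by chr3:24230801-24231600 with 4.98, chr1:29592001-29592800 with 4.43, chr10:109027201-109028400 with 4.27 and chr4:51444201-51445400 with 4.14. In round spermatids chr10:56895801-56897000 had a fold of 8.01 (3.98 to 18.3, 68 and 9 reads), followed by chr13:39206001-39207000 with 4.85, chr12:12941001-12941800 with 4.68, chr18:55217401-55218800 with 4.54 and chr6:10120401-10121600 with 4.50. In wild-type germ cells chr12:116851201-116852200 had a fold of 11.1 (4.49 to 35.6, 55 and 5 reads), followed by chr9:82733201-82733800 with 6.82, chr8:54523801-54524800 with 5.81, chr6:60896801-60897600 with 5.70 and chr4:50081001-50082600 with 5.66. The chr16, chr3 and chr10 islands of spermatocytes, and the first 3 islands of round spermatids, were the highest with no island in the other tagged list. The chr12, chr9 and chr8 islands were the highest wild-type islands with none in either tagged list. The chr1 island of spermatocytes overlapped a round spermatid island and the chr4 island of wild-type germ cells overlapped a tagged one.

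The longest islands had folds below the median of their list. In spermatocytes they were chrY:2847401-2902600, chr9:2999801-3038600, chrY:1257801-1289600, chrY:2768201-2797600 and chr4:60064601-60094000, with folds of 1.05, 1.41, 1.05, 1.06 and 1.08. In round spermatids they were chr11:3025801-3100400, chrY:2847401-2902600, chr3:25413801-25457600, chrX:121918001-121960400 and chr9:2999801-3038600, with folds of 1.07, 1.09, 1.07, 1.09 and 1.21. In wild-type germ cells 3 of the longest lay close together, at chr4:146519201-146551000, chr4:146750401-146780400 and chr4:146810001-146839400, with folds of 1.09, 1.09 and 1.08. The others were chr5:94345801-94373800 and chrY:2776801-2797600, with folds of 1.06 and 1.04.

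The first comparison asked how TH2B binding in meiotic cells related to binding in post-meiotic cells. Most islands of each tagged list had no overlapping island in the other, but the overlap was above that of shifted islands. Of the spermatocyte islands, 2686 overlapped a round spermatid island (17.2%, 16.6 to 17.8), beside a mean of 5.16% and a range of 4.67% to 5.81% after random shifts within chromosomes. Of the round spermatid islands, 2694 overlapped a spermatocyte island (15.5%, 15.0 to 16.1), beside 4.64% (range 4.16% to 5.07%) after shifts. The observed counts were 3.34 and 3.35 times the shifted means. When islands were moved by only 50 to 500 kb, a comparison chosen after the data were seen, the means were 7.55% and 6.88%, and the observed counts were 2.28 and 2.26 times them.

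Overlap was least frequent among islands of high fold. It was 19.8% (18.9 to 20.7) of spermatocyte islands with a fold under 1.5, 15.4% (14.5 to 16.3) between 1.5 and 2, and 11.7% (10.03 to 13.5) at 2 or more. For round spermatid islands the shares were 17.2% (16.4 to 17.9), 13.8% (12.9 to 14.7) and 11.04% (9.25 to 13.0). Islands of high fold were also shorter, with median lengths of 4000, 3200 and 2400 bp in the 3 classes of spermatocyte islands and 3800, 3000 and 2200 bp in those of round spermatids, and the shifted shares fell too, from 5.66% to 4.32% and from 4.98% to 3.73%. Restricted to islands with a fold of at least 2 in both lists, 10 of 1378 spermatocyte islands (0.726%, 0.349 to 1.33) overlapped, beside 0 to 9 after shifts.

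**Figure D1:**
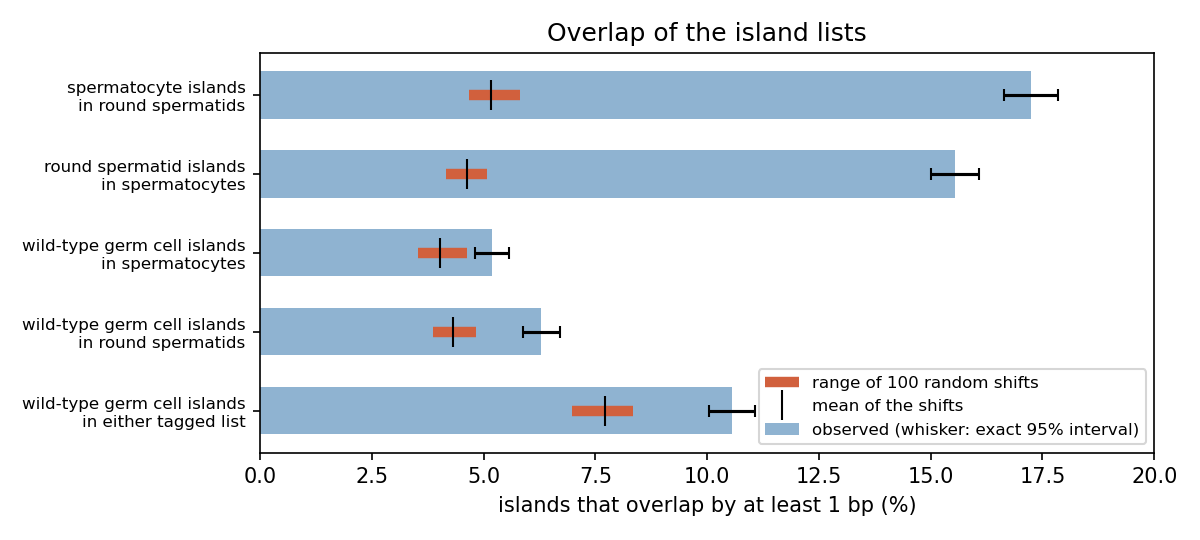
Share of islands of each list (%) that overlap an island of another list by at least 1 bp; bars are observed shares with exact 95% intervals as whiskers, thick lines are the range of 100 random shifts within chromosomes and ticks their mean. The tagged lists overlapped each other by 17.2% and 15.5%, and wild-type islands overlapped either tagged list by 10.6%.

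Where both tagged lists had islands, their folds had already passed the caller's threshold in both, so these ratios leave out regions called in 1 list only. In the 2645 shared regions the median fold was 1.46 in spermatocytes and 1.42 in round spermatids, and the ratio of round spermatids to spermatocytes had a median of 0.985, with a 5th percentile of 0.710 and a 95th of 1.33. A change of at least 2-fold was reached by 5 regions higher in round spermatids and 9 higher in spermatocytes, 0.529% of the regions. Among simulated unchanged regions the share was 0.336%. The simulation drew both libraries from the same spermatocyte islands and applied no caller's threshold to them. Its share is therefore not the one that chance gives for these regions. The counting interval of the ratio left out 1 in 47 regions higher in round spermatids and 86 higher in spermatocytes, 5.03% of the regions. Chance gives 5% only for unselected ratios of the same stretch, so the 2 shares cannot be set against each other here. Across the regions, which are not independent replicates, the log2 folds of the lists correlated with a Pearson r of 0.244 and the folds with a Spearman rho of 0.264. The choice of regions called in both lists favours ratios near 1, so these shares do not measure how far the cell types differ. At 3-fold, 1 region was higher in round spermatids and 0 in spermatocytes, and with at least 100 ChIP reads in each list 2 and 0. These counts are too small to give a direction. The 5 regions higher in spermatocytes that are named below had 53 to 70 spermatocyte ChIP reads, so the filter on reads removes them. With ChIP reads scaled to all ChIP reads in islands in place of the fold over input, 79 regions were higher in round spermatids and 195 in spermatocytes. Such reads grow with the length of an island, and per kb of island, a setting chosen after the data were seen, the counts were 17 and 33. A further 12899 spermatocyte islands and 14646 round spermatid islands lay in no shared region.

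In the region chr14:117370401-117376800 the round spermatid islands had a fold of 4.30 and the spermatocyte islands 1.24 (ratio 3.47, interval 1.94 to 6.20). The next were chr13:6328201-6332600 with a ratio of 2.66 (1.71 to 4.12), chr11:81958201-81964000 with 2.55 (1.53 to 4.23), chr16:75032401-75035000 with 2.28 (1.35 to 3.85) and chr13:40778001-40784400 with 2.27 (1.47 to 3.53). In the other direction, in the region chr12:72820401-72826400 the round spermatid islands had a fold of 1.23 and the spermatocyte islands 3.63 (ratio 0.338, 0.195 to 0.586). This region was followed by chr5:12572801-12578600 with 0.425 (0.255 to 0.707), chr15:21366001-21368600 with 0.452 (0.253 to 0.807), chr1:29589801-29594200 with 0.455 (0.236 to 0.875) and chr1:110682001-110686000 with 0.458 (0.274 to 0.765). These are the extremes of 2645 ratios, and their intervals are not corrected for that choice. The 2 folds of a region come from each list's own islands, which can differ in place and length. At chr1:29589801-29594200 the spermatocyte fold of 4.43 was that of the island chr1:29592001-29592800 alone, of 800 bp. The ratios therefore do not always compare the same stretch of DNA in both cell types.

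**Figure D2:**
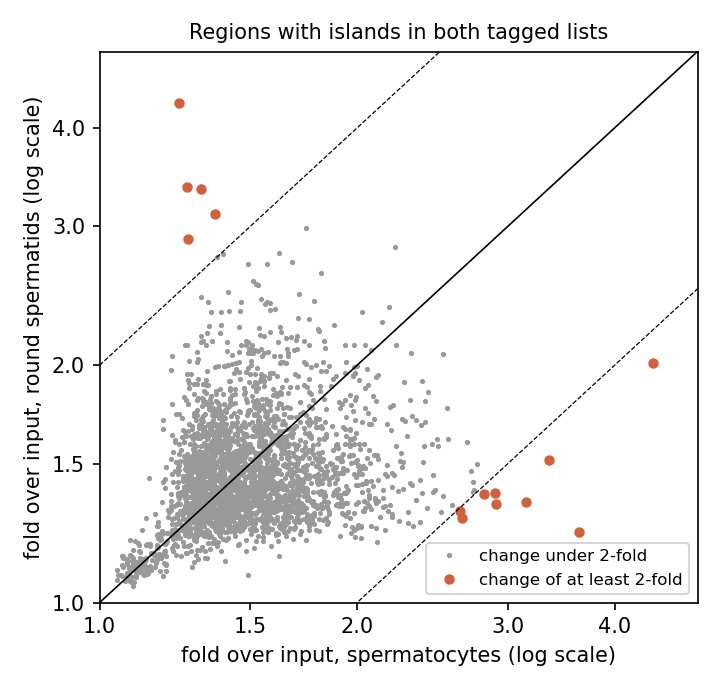
Fold over input in spermatocytes (x axis, log scale) and in round spermatids (y axis, log scale) for 2645 regions with islands in both tagged lists. Each point is a region, and each fold is that of the list's own islands in it. The solid line marks equal folds and the dashed lines a 2-fold change. The 14 regions outside the dashed lines are the 5 higher in round spermatids and the 9 higher in spermatocytes, and the other points spread around the line of equal folds.

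The second comparison set native TH2B in wild-type germ cells beside the tagged protein. Cells, antibody and genotype all differed between these libraries. Wild-type islands overlapped tagged islands little, and more often than shifted islands did at the authors' threshold. The excess was smaller at a stricter FDR, and at a fold of at least 2 too few islands overlapped to tell. Of the 13582 wild-type islands, 704 overlapped a spermatocyte island (5.18%, 4.82 to 5.57; shifts 3.54% to 4.64%) and 855 a round spermatid island (6.30%, 5.89 to 6.72; shifts 3.87% to 4.82%). Either tagged list was overlapped by 1433 (10.6%, 10.04 to 11.1), beside a mean of 7.70% after shifts, a ratio of 1.37. Against moves of 50 to 500 kb the ratio was 1.57. Islands present in all 3 lists were few, with 140 spermatocyte islands (0.898%) overlapping both other lists. At an FDR of 0.0001, 141 of 6028 wild-type islands overlapped a spermatocyte island, within the 90 to 142 of the shifts, 157 a round spermatid island (shifts 95 to 152) and 283 either (shifts 202 to 280). At a fold of at least 2, 6 overlapped a spermatocyte island (shifts 0 to 6, mean 1.94) and 1 a round spermatid island (shifts 0 to 5, mean 1.44). At that fold 7 of 849 wild-type islands overlapped either tagged list, beside a shifted mean of 3.34, and as many did in at least 1 of the shifts. The moves of 50 to 500 kb were not made at these stricter settings.

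Some chromosomes carried different densities of islands in tagged and wild-type lists, and others like ones. The chromosomes named here were chosen after the values were seen. Chromosome 1 had 8.16 islands per Mb in spermatocytes and 10.3 in round spermatids, the highest of the autosomes in both, and 4.64 in wild-type germ cells. Chromosome 11 had 4.40, 5.02 and 7.12 islands per Mb, the last being the highest wild-type value. Chromosome 3 had 7.43, 8.02 and 3.96, and chromosome 9 had 4.66, 5.43 and 6.54. By contrast, chromosome 12 had 5.88 in spermatocytes, 6.61 in round spermatids and 5.88 in wild-type germ cells, and chromosome 2 had 6.39, 6.56 and 5.99.

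**Figure D3:**
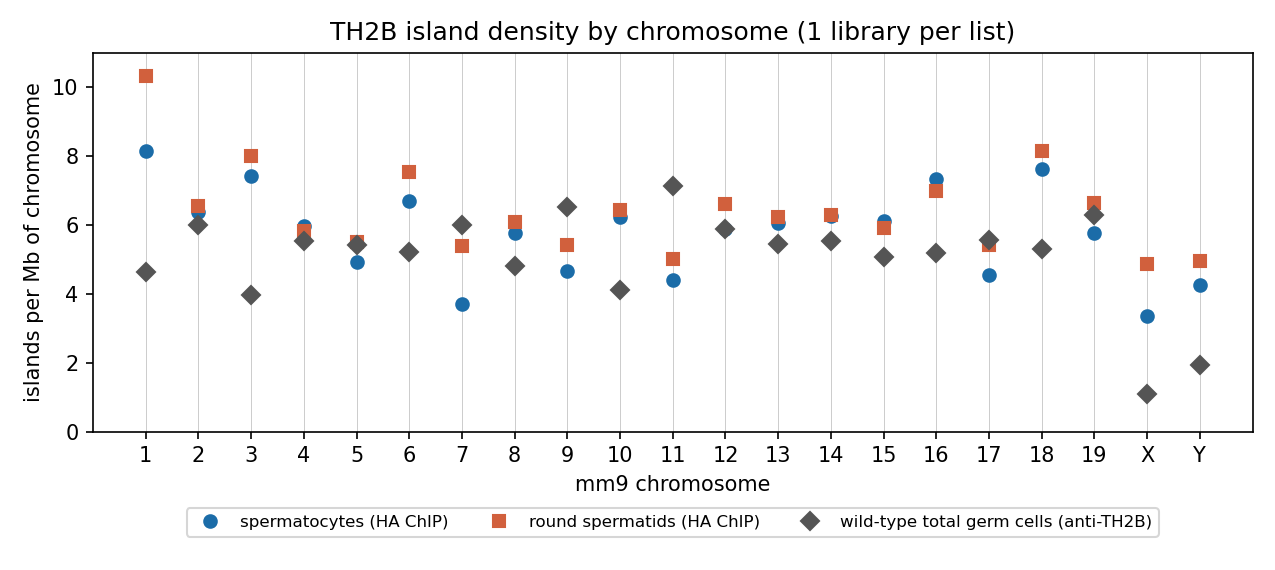
Islands per Mb of each mm9 chromosome in the 3 lists, 1 point per list and chromosome. Chromosome 1 is highest in both tagged lists at 8.16 and 10.3 and low in the wild-type list at 4.64, and X is low in all 3 at 3.37, 4.88 and 1.10.

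The third comparison concerned the sex chromosomes, which are transcriptionally silenced during meiosis. X is also a single-copy chromosome in male cells, which lowers the density of reads on it. The ratios below cannot tell copy number from a lower level of TH2B, and a link to silencing was not tested. Islands covered a smaller share of X than of the autosomes in all 3 lists. In spermatocytes 1.12% of X and 2.30% of the autosomes were covered, a ratio of 0.487 (0.446 to 0.529, from the count of X islands). In round spermatids the shares were 1.73% and 2.43%, a ratio of 0.713 (0.664 to 0.765). In wild-type germ cells they were 0.270% and 1.49%, a ratio of 0.181 (0.156 to 0.210). The covered share of single autosomes spread widely, which these intervals do not cover. It ran from 1.41% on chromosome 7 to 3.24% on chromosome 1 in spermatocytes. In round spermatids it ran from 1.88% on chromosome 11, close to the 1.73% of X, to 3.92% on chromosome 1. In wild-type germ cells it ran from 1.06% on chromosome 3 to 1.97% on chromosome 11. The X islands numbered 561 in spermatocytes and 814 in round spermatids, 1.45 times as many (1.30 to 1.62), while the autosomes together gave a ratio of 1.10. Single autosomes ranged from 0.953 on chromosome 16 to 1.46 on chromosome 7 (1.31 to 1.62), which was as high as X. With a fold of at least 2 the ratio of X to autosomes was 0.0831 in spermatocytes, 0.0982 in round spermatids and 0.0966 in wild-type germ cells.

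X islands lay where the input was dense. Their median input density was 54.7 reads per kb in spermatocytes, 57.5 in round spermatids and 58.7 in wild-type germ cells, beside 22.5, 25 and 32.7 in autosomal islands. Their median fold was 1.33, 1.32 and 1.43, beside 1.51, 1.47 and 1.45. From 140 Mb to the end, 16.0% of the chromosome, X held 303 spermatocyte islands (54.0% of those on X, 49.8 to 58.2), 414 round spermatid islands (50.9%, 47.4 to 54.3) and 63 wild-type islands (34.4%, 27.6 to 41.8). Without this part the covered ratio of X to autosomes was 0.242 in spermatocytes, 0.411 in round spermatids and 0.183 in wild-type germ cells. Input density in the last 5 Mb bin, from 165 Mb, had a median of 330 reads per kb in spermatocyte islands and 265 in round spermatid islands. Chromosome Y had 68, 79 and 31 islands in spermatocytes, round spermatids and wild-type germ cells, with median folds of 1.17, 1.14 and 1.34 and median input densities of 126, 143.0 and 98.8 reads per kb.

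**Figure D4:**
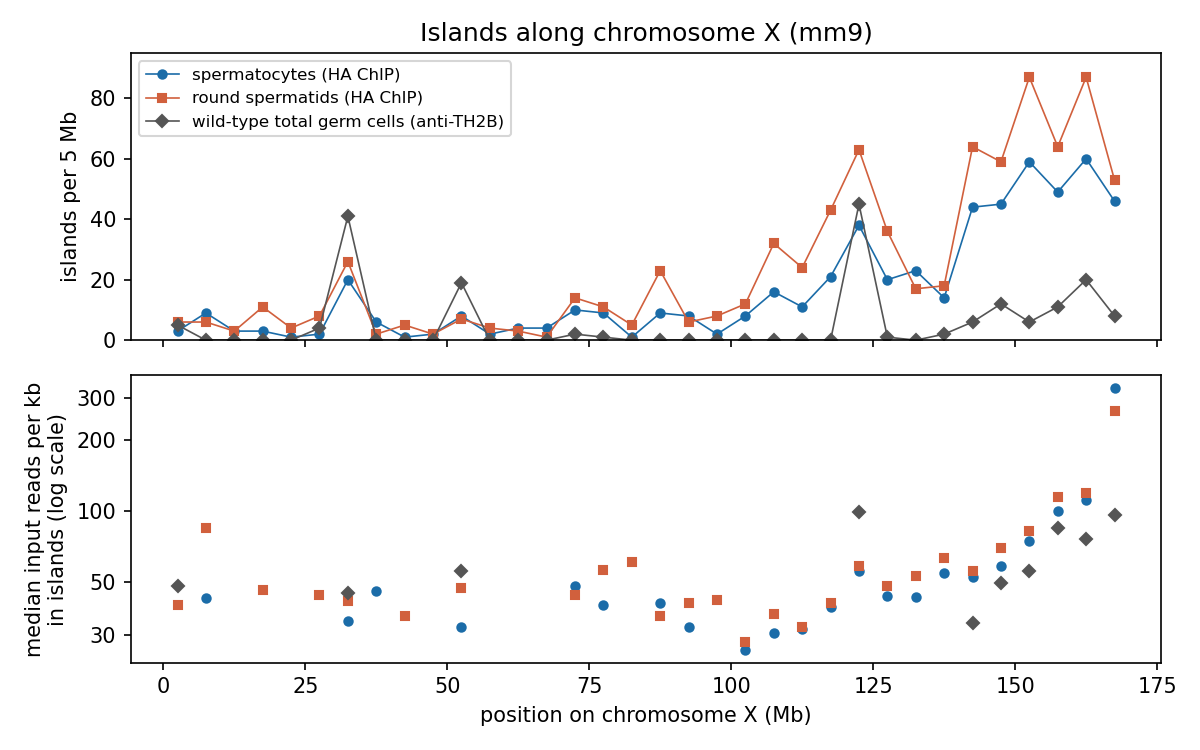
Islands per 5 Mb (upper panel) and median input reads per kb within islands (lower panel, log scale, bins with at least 5 islands) along mm9 chromosome X in the 3 lists. Islands of the tagged lists are frequent from 140 Mb on, where the input density rises to 330 reads per kb in spermatocytes and 265 in round spermatids.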

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

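Of 57 alternatives, 19 left a value within its counting interval or within 1.5 times the count, and 38 moved it. The X to autosome ratio stayed below 1 in all of its alternatives. Regions higher in round spermatids and in spermatocytes, 5 and 9, became 1 and 0 and 2 and 0 under 2 settings below. These counts are too small to give a direction. The excess of wild-type overlaps over shifts was smaller at the stricter FDR, and at a fold of at least 2 too few islands overlapped to tell. The alternatives on autosomes, read-rich islands, input density, the end of X and reads per kb were chosen after seeing the data. At an FDR of 0.0001 the lists held 7679 (spermatocytes), 8321 (round spermatids) and 6028 (wild-type) islands, and at a fold of at least 2 they held 1378, 1105 and 849, since both are subsets. Spermatocyte islands shared with round spermatids were 9.87% with 50% reciprocal overlap, 15.4% with equal numbers of islands, 8.58% at the stricter FDR, 0.726% at a fold of at least 2, 16.6% on autosomes and 16.2% on autosomes at up to 2 times the median input density. Round spermatid islands shared with spermatocytes were 8.88% with reciprocal overlap, 7.91% at the stricter FDR, 0.905% at a fold of at least 2 and 14.9% at usual input density. Wild-type islands shared with either tagged list were 4.56%, 4.69%, 0.824% and 9.999% under those 4 settings. Smaller subsets overlap less by construction. The X to autosome ratio in spermatocytes was 0.556 by islands per Mb, 0.259 at the stricter FDR, 0.0831 at a fold of at least 2 and 0.242 without the end of X. In round spermatids it was 0.470, 0.0982 and 0.411 under the last 3, and in wild-type germ cells 0.0966 at a fold of at least 2. The cause was not tested.

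Shared regions higher in round spermatids and in spermatocytes numbered 49 and 87 at 1.5-fold and 1 and 0 at 3-fold. They numbered 79 and 195 by scaled ChIP reads and 17 and 33 by scaled ChIP reads per kb. Among the 1513 regions with at least 100 ChIP reads in each list they numbered 2 and 0. Thresholds change these counts by construction. Scaled reads grow with the length of the island, and the cause of the rest was not tested. Depth limits the folds, since the median shared region had 122 ChIP reads. The share of islands at transcription start sites and its alternatives were not run, for want of gene models of this build here. No paired analysis was possible because each group had 1 library and no result came from a test.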

Other observations

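All tests in this part were chosen after the results were seen, and each explanation is a hypothesis.

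Reads were concentrated in a few regions of the tagged lists. Islands with at least 1000 ChIP reads numbered 101 in spermatocytes, 161 in round spermatids and 46 in wild-type germ cells, and held 24.9%, 25.6% and 6.14% of the ChIP reads in islands, with median folds of 1.11, 1.10 and 1.12. The island at chr9:2999801-3038600, at the start of the assembled chromosome, alone held 229021 ChIP reads in spermatocytes (9.64% of the list) and 233148 in round spermatids (7.62%), with folds of 1.41 (1.40 to 1.42) and 1.21 (1.20 to 1.21). The island at chr2:98501401-98507600 held 60207 reads in spermatocytes at a fold of 1.26, and the round spermatid island over it 63576 at 1.18. The wild-type list had 0 islands at both places.

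Part of chromosome 7 differed between the tagged lists. Its first 40 Mb held 84 spermatocyte islands and 250 round spermatid islands, 2.98 times as many (2.32 to 3.86), and 178 wild-type islands. The rest of the chromosome held 483 and 575, a ratio of 1.19 (1.05 to 1.35). The part was picked for its ratio, so the interval overstates how far it stands apart. Its bins of 10 Mb had ratios from 2.22 to 5. Single bins on other chromosomes also had high ratios, on fewer islands than the whole part. One was 2.75 at 70 to 80 Mb of chromosome 11, from 8 spermatocyte and 22 round spermatid islands. Another was 2.72 at 20 to 30 Mb of chromosome 12, from 29 and 79. Others were low, such as 0.345 at 20 to 30 Mb of chromosome 5, from 29 and 10. On X, the 3 bins of 5 Mb with most wild-type islands, which start at 30, 120 and 160 Mb, held 106 of the 183 wild-type islands (57.9%, 50.4 to 65.2), 118 of 561 spermatocyte islands (21.0%, 17.7 to 24.6) and 176 of 814 round spermatid islands (21.6%, 18.8 to 24.6). These bins were picked for their wild-type islands, which raises the wild-type share.

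Islands of the tagged lists and of the wild-type list lay in different parts of the autosomes. Over 239 bins of 10 Mb, which are not independent replicates, the number of islands correlated between spermatocytes and round spermatids with a Pearson r of 0.856 (Spearman rho 0.860), but between wild-type germ cells and spermatocytes with -0.571 (-0.587), and between wild-type germ cells and round spermatids with -0.480 (-0.494). Read-rich repeats kept in one set of lists are argued against only as far as islands of over 2 times the median input density, which were few: without them 14811 of 14956 spermatocyte, 16222 of 16447 round spermatid and 13281 of 13368 wild-type islands were left on autosomes, and the higher of the 2 correlations with the wild-type list was -0.481. Repeats at usual density were not tested. Weak islands near the caller's threshold are argued against only as far as islands with an FDR above 0.0001, because without them the higher was -0.479. That cut kept 49.3% of spermatocyte, 48.0% of round spermatid and 44.4% of wild-type islands. With the few islands of fold 2 or more the values were only -0.137 and -0.0596, and that between the tagged lists was also lower, at 0.462. Whether islands of low fold make the pattern was therefore left undecided. Base composition, the antibody, the genotype, the cells and the preparation of the libraries stay open, since no genome sequence of this build was used here and the others differ together between the lists.

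The X chromosome had few islands, at positions of dense input, and more of them in round spermatids than in spermatocytes. A read density that islands must reach whatever the copy number of the chromosome could give the first part, but this was left undecided. At least 99.6% of X islands, in both tagged lists, had the ChIP density of the 5th percentile of autosomal islands or more, but listed islands had all passed the caller's threshold, so a high share decides nothing. The median ChIP density of X islands, 63.8 reads per kb in spermatocytes and 74.3 in round spermatids, lay above the 29.4 and 35.3 of autosomal islands, and not at such a floor. That explanation and a lower level of TH2B on X both stay open, because reads outside islands were not used here. For the second part, a spread between chromosomes of the tagged libraries that also touches autosomes was left undecided. The interval of the ratio of round spermatid to spermatocyte islands left out the ratio of all autosomes in 5 of 19 autosomes, with chromosomes 1 and 7 above and 4, 15 and 16 below. Counting error alone gives 0.95, but islands cluster, so more may be found in any pair of libraries. A first test, the number of autosomes with a ratio at least that of X, gave 1, which was chromosome 7. A difference between the cell types in TH2B on X stays open and was not tested apart from the libraries.

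Chromosome 1 had the most islands per Mb of the 19 autosomes in both tagged lists, 8.16 and 10.3 beside a median of 6.02 and 6.27 in the others. More input reads per kb on chromosome 1 may contribute, since its islands had the highest median input density and the lowest median fold of the autosomes in both lists, but the density was only 1.04 times the median of the others in spermatocytes and 1.05 times in round spermatids. In wild-type germ cells it was 0.988 times that median. Among the other autosomes, input density and islands per Mb did not always go together. Chromosome 19 had their highest density, 23.0 reads per kb in spermatocytes and 25.7 in round spermatids, with 5.77 and 6.65 islands per Mb. Chromosome 3 had 22.2 and 24.5, which no autosome fell below, with 7.43 and 8.02 islands per Mb. Chromosome 18 went the other way, at 22.7 and 25.3 with 7.62 and 8.16 islands per Mb. Input was measured only within called islands, a gain of this size was not shown to be enough, and a difference of TH2B on chromosome 1 between the tagged and the wild-type lists stays open, untested.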
